A study of Mus musculus with 8 samples.

How the data were processed

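Gene expression was measured in mouse embryo tissue from the region of rhombomeres 3 to 5, the hindbrain segments next to the forming inner ear, dissected with its neuroectoderm, mesoderm and otic ectoderm. Embryos had 1 to 6 somites. Each genotype, wildtype or homozygous for a null allele of Hoxa1 (Hoxa1 null), was represented by 24 embryos in 4 pools, and each pool held 6 embryos, 1 of each somite stage. Per the labels, total RNA was cleaned of DNA on the column, labelled with Cy3 by a one-colour amplification kit and hybridised to 1 Agilent array per pool, so that there were 8 arrays. The strain of the mice and how the null allele was made are not given in the sources used here.

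The authors deposited 1 scanner table per array, made with Agilent Feature Extraction 10.5.1.1. Per the file headers, the processed signal is an intensity in scanner units, background subtracted and detrended within the array, with surrogate values for dim spots and no scaling between arrays. The same deposited tables give the raw mean signal and the median local background of each spot, also as intensity. The deposited value table of the series holds log2 values: compared with the scanner tables, they equalled the log2 processed signal averaged over the spots of a probe, with no scaling between arrays and 34 empty cells. Every array had 43379 spots that were not controls, for 41174 probes. Probe positions are on mm9, as named in the file headers.

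From the scanner tables, control spots and spots marked as outliers (40 to 119 per array) were left out, and log2 processed signals were averaged over the spots of a probe. The 75th percentile of each array was subtracted, so that every level below is a log2 signal relative to that percentile. Probes were given current gene symbols from RefSeq accessions (25097 probes), by symbol (6333) or by a synonym (1640); 8104 probes kept the name in the file, and 27729 distinct names resulted. The reference table of the GRCm38.p6 annotation was used for names only. A probe was tested when it was well above background, by the scanner's own mark, on all 4 arrays of at least 1 genotype, and a gene was represented by its tested probe of highest mean. This left 28110 probes and 18861 genes.

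Hoxa1 null pools were compared with wildtype pools with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table), by a linear model with genotype as the only term and moderated variances, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p of a gene below comes from this limma model. A gene below background on all arrays of a genotype is given as a bound. On each of those arrays its signal was replaced by the lowest signal that passed as well above background, unless its own was higher. The bound is a difference of means without an allowance for error. Lists of genes, 31 in all, were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, on ranks, and with fry; a list needed 5 tested members. Means of a list per pool were compared by an exact permutation test over the 70 assignments of the pools, two-sided, whose smallest possible p is 0.0286.

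The genes named were chosen by a rule that was also fixed before the data were examined. It takes Hoxa1, the 10 largest falls and the 10 largest rises among genes past the threshold whose 4 pools of one genotype all lie beyond those of the other, and up to 4 members of each list by lowest p (8 in the lists of anterior Hox genes, segmental hindbrain genes and the retinoic acid pathway). Clone names are counted and not named. Exceptions are marked where they occur.

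The arrays came from 2 slides, and each slide held 2 pools of each genotype, wildtype and Hoxa1 null pools 1 and 2 on one and pools 3 and 4 on the other. Genotype differences were therefore also computed with the slide as a block and within each slide. Replicate numbers were checked as pairs and not used as such, since deviations of pools with the same number correlated at 0.17, -0.07, -0.05 and 0.43.

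Alternatives were quantile normalisation, median centring, normexp background correction with an offset of 50 (before the 75th percentile or before quantile normalisation), no background filter, a filter on all 8 arrays, the mean of a gene's probes, every probe by itself, the deposited value table, the slide as a block, each slide by itself, the replicate number as a block, a variance trend with robust estimation, array weights, thresholds of 0.01 and 0.1, a minimum fold of 1.5, and leaving out each pool in turn. Chosen after seeing the data were covariates for yolk sac genes and for decidua and trophoblast genes, leaving out Hoxa1 null pools 2 and 4 together, the retinoic acid list without Rbp4, normexp fitted by maximum likelihood, and normexp without spots of bright local background.

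The share of probes well above background was 68.6% to 72.7% per array, the 75th percentile of the processed signal was 680.4 to 964 scanner units, the fit of the spike-in series had an r² of 0.993 to 0.994, and the median coefficient of variation of replicated probes was 3.69% to 4.93%. The number of arrays limits the precision. Data were simulated for 18861 genes, each drawn independently with its moderated variance from the limma model. Of these, 34.3% of genes shifted by 0.5 log2 units were called, 71.6% of those shifted by 1 and 95.5% of those shifted by 2, with 6 false calls. The simulation leaves out variation between pools that genes share, so these shares may not hold for the data.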

Results

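The data comprised 8 arrays, 4 from pools of wildtype embryos and 4 from pools of Hoxa1 null embryos, with tissue of the rhombomere 3 to 5 region at 1 to 6 somites. Pearson's r between arrays, across genes, was 0.991 to 0.995 among wildtype pools, 0.979 to 0.995 among Hoxa1 null pools and 0.979 to 0.994 between genotypes. The single comparison of the design asks which genes differ in level between Hoxa1 null and wildtype tissue of this region.

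Hoxa1, the homeobox gene for which the embryos were null, fell by 6.00 on the log2 scale (SE 0.11, n = 4 pools per genotype, 64.1-fold), with an adjusted p of 1.9e-07. Its mean level was 3.58 ± 0.10 (SD, n = 4) in wildtype and -2.42 ± 0.21 (SD, n = 4) in Hoxa1 null pools, and its single probe lies on chromosome 6 from 52105768 to 52105827. The probe was well above background on all 8 arrays. Within the slides, the change was -6.01 and -5.99.

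In Hoxa1 null tissue, the hindbrain genes Mafb, Hoxb1 and Hnf1b, the neural crest gene Foxd3 and the otic gene Pax8 fell, and Hoxa2 and an antisense transcript of the Hoxa cluster rose. Mafb, a transcription factor of rhombomere 5, fell by 2.61 on the log2 scale (SE 0.35, adjusted p = 0.0266, n = 4 per genotype), and Foxd3, a transcription factor of early neural crest, fell by 2.12 (SE 0.26, adjusted p = 0.0188). Hoxa2, the neighbour of Hoxa1 in the cluster, rose by 1.97 (SE 0.11, adjusted p = 0.000366), and Hoxaas2, an antisense transcript of the cluster, rose by 2.46 (SE 0.17, adjusted p = 0.00157). Nkx6-2, a homeobox gene of the ventral neural tube, rose by 1.37 (SE 0.20, adjusted p = 0.0402). Of these genes, Hoxa2 and Hoxaas2 passed in all 8 fits with 1 pool left out. Foxd3 passed in 4, Mafb, Pax8 and Nkx6-2 in 2, and Hoxb1 and Hnf1b in 1.

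Of 18861 genes, 77 passed, 51 of them lower and 26 higher in Hoxa1 null pools. Of the 77, 6 carried clone names as the naming rule defined them, and 65 differed by at least 1.5-fold. That definition missed some names that are also only identifiers, so 6 is a minimum. Among all 18861 genes, 2870 had an unadjusted limma p under 0.05. In all 77 the pools of one genotype lay beyond those of the other, as they did in 8.89% of all genes tested, where chance gives 2.86%. With the slide as a block, 72 genes passed, and 2 genes passed in slide 1 and 1 in slide 2, each with 2 pools per genotype. The count was 31, 40, 31 and 153 without wildtype pools 1, 2, 3 and 4, and 28 and 29 without Hoxa1 null pools 1 and 3. It was 38 with no background filter, 143 with a variance trend, 266 with array weights and 1 (lower) after normexp with the 75th percentile, where the median of all genes shifted by 0.15. In the value table, which is not scaled and shifts that median by -0.13, 58 genes passed, 51 lower and 7 higher. With the mean of the yolk sac list as a covariate, 29 passed, and 33 passed with decidua and trophoblast covariates.

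Among the other large falls, Gabrg1, a subunit of the GABA receptor, fell by 2.12 (SE 0.11, adjusted p = 0.000366), and Lhx5, a LIM homeobox gene, fell by 2.01 (SE 0.15, adjusted p = 0.0023). Chrna5, a nicotinic acetylcholine receptor subunit, fell by 1.71, Dner, a transmembrane protein with EGF repeats, fell by 1.44, and Krt5, a keratin of stratified epithelium, fell by 1.43. Cryba2, a crystallin, was at least 1.97-fold lower and Fezf2, a zinc finger gene of the forebrain, at least 2.10-fold lower, since both were below background on the Hoxa1 null arrays. Rises were seen in Nuak1, a kinase (1.02), and Slc25a45, a mitochondrial carrier (0.98). Tmod1 (at least 2.59-fold), Drd5 (at least 1.98-fold) and the globin pseudogene Hba-ps4 (at least 2.14-fold) were higher in Hoxa1 null pools and below background in wildtype. Olfr648 (1.31) and Cfap100 (1.00) were above background on 2 and 3 of the wildtype arrays. With 1 pool left out at a time, Gabrg1, Lhx5, Chrna5, Cryba2, Dner, Hoxa2, Hoxaas2 and Nuak1 passed in all 8 fits. Foxd3 passed in 4, Krt5, Fezf2 and Hba-ps4 in 5, Mafb, Nkx6-2, Drd5 and Olfr648 in 2, and Tmod1, Cfap100 and Slc25a45 in 1.

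**Figure D1:**
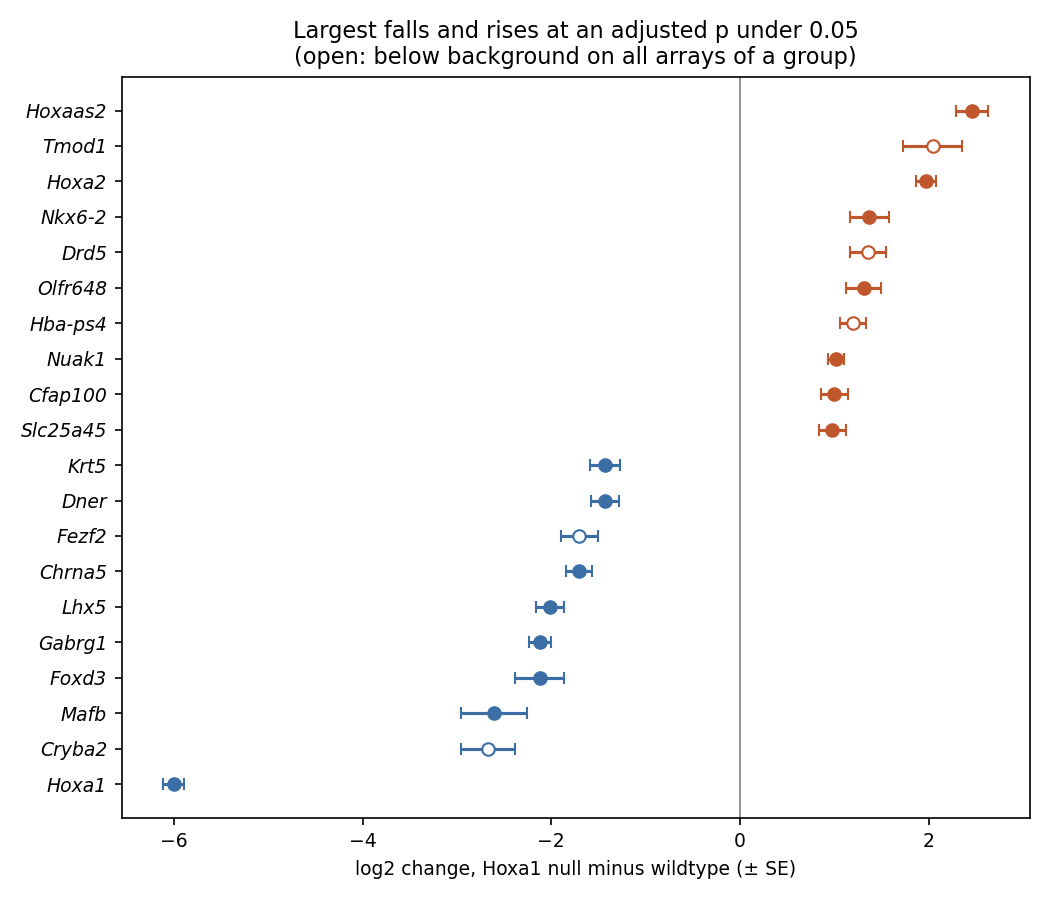
Log2 change (Hoxa1 null minus wildtype, horizontal axis) of the named genes with the largest falls and rises, as points with the SE of the limma fit (n = 4 pools per genotype). Open points are genes below background on all arrays of a genotype, whose change is a bound in the text; Hoxa1 lies at -6.00 and Hoxaas2 at 2.46.

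Of 10 tested anterior Hox genes other than Hoxa1, 1 rose (Hoxa2) and 1 fell (Hoxb1); adjusted over the list alone, 3 rose and 3 fell. Hoxb1, the Hox gene of rhombomere 4, fell by 1.17 (SE 0.17, adjusted p = 0.0309, mean 0.37 ± 0.07 SD in wildtype and -0.80 ± 0.36 SD in Hoxa1 null, n = 4). Hoxb2 differed by -0.91 (adjusted p = 0.0835), Hoxb3 by -0.49 (adjusted p = 0.122), Hoxa3 by 0.16 (adjusted p = 0.457) and Hoxb4, above background on 1 wildtype array, by 1.31 (adjusted p = 0.18). A dimmer probe of Hoxb2 differed by 0.03, and another probe of Hoxa3, at a similar mean level (-3.48 against -3.32), by 1.00. Under normexp with the 75th percentile, Hoxb3 differed by 0.04. The list did not pass (camera adjusted p = 0.862, median 0.05), and Hoxb1 passed in 1 of 8 fits with a pool left out, the one without Hoxa1 null pool 4.

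Among 29 tested genes of the segmented hindbrain, 4 fell and 1 rose; adjusted over the list alone, 7 fell and 3 rose, and the list did not pass (camera adjusted p = 0.103, median -0.06). The list mean was lower in each Hoxa1 null pool than in any wildtype pool (difference -0.20, -0.18 in slide 1 and -0.21 in slide 2, exact permutation p = 0.0286). Besides Mafb and Hoxb1, the falls were Epha2, an Eph receptor (-0.94, SE 0.09, adjusted p = 0.00617), and Hnf1b, a homeobox gene of the caudal hindbrain (-1.33, SE 0.20, adjusted p = 0.0373). The dimmer probe of Hnf1b differed by 0.03, and Hnf1b passed in 1 of 8 fits with a pool left out. Egr2, the zinc finger gene of rhombomeres 3 and 5, differed by 0.60 (SE 0.13), which did not pass (adjusted p = 0.131).

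**Figure D2:**
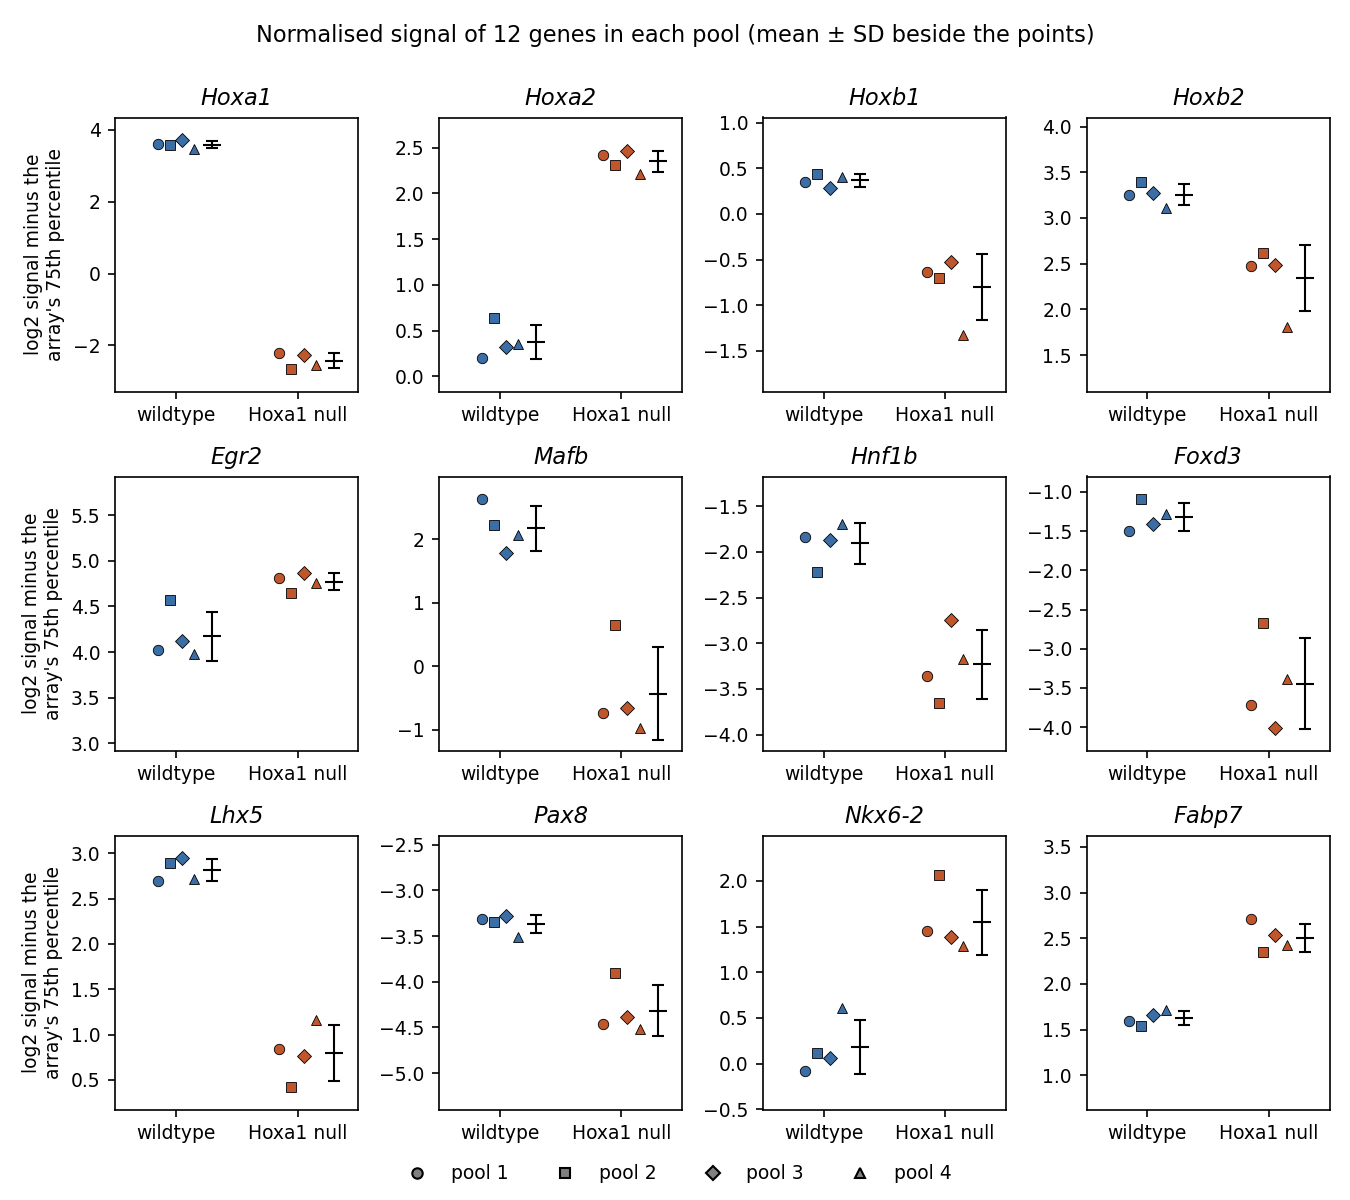
Log2 signal relative to the array's 75th percentile (vertical axis, own scale in each panel) of 12 genes in the 4 wildtype and 4 Hoxa1 null pools, with mean ± SD beside the points. Wildtype pools average 3.58 for Hoxa1 and 0.38 for Hoxa2, and Hoxa1 null pools average -2.42 and 2.35; Hoxb2 and Egr2 did not pass.

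Neural progenitor genes were higher as a list (camera adjusted p = 0.00225, median 0.25), with Fabp7 and Nkx6-2 rising among 22 tested; adjusted over the list alone, 10 rose and 1 fell. With an estimated correlation, the camera adjusted p was 0.264 (unadjusted 0.0085). That correlation was 0.00865, below the preset 0.01, so a stronger correlation among the members does not account for the higher p. Fabp7, a fatty acid binding protein of radial glia, rose by 0.87 (SE 0.09, adjusted p = 0.0095), while Sox1 differed by 0.57 (adjusted p = 0.0668) and Sox2 by 0.34 (adjusted p = 0.12). The list mean was higher in each Hoxa1 null pool than in any wildtype pool (difference 0.36, exact permutation p = 0.0286, the smallest possible), by 0.38 in slide 1 and 0.35 in slide 2. Its call was lost after normexp with the 75th percentile (median 0.04, adjusted p = 0.575). It was kept once 14 spots of bright local background on the Hoxa1 null 1 array were left out (median 0.24, adjusted p = 0.00684).

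Otic and preplacodal genes were lower as a list (camera adjusted p = 0.00421, median -0.20, adjusted p = 0.418 with an estimated correlation). Of 28 tested, Pax8, a paired box gene of the otic field, fell by 0.95 (SE 0.14, adjusted p = 0.0352); adjusted over the list alone, 2 fell and 0 rose, and Eya1 differed by -0.35 (adjusted p = 0.127). The list mean differed by -0.17 in slide 1 and -0.12 in slide 2 (exact permutation p = 0.0286). After normexp with the 75th percentile, the list did not pass (median 0.02, adjusted p = 0.204) and Pax8 differed by 0.33. Without the 14 bright spots, the list passed (median -0.16, adjusted p = 0.00281) and Pax8 differed by -0.34 (adjusted p = 0.196). In addition, Pax8 passed in 2 of 8 fits with a pool left out.

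Genes of the FGF pathway were lower as a list (camera adjusted p = 0.00449, median -0.24, adjusted p = 0.418 with an estimated correlation). Dusp4, a phosphatase induced by MAP kinase signalling, fell by 0.76 (SE 0.07, adjusted p = 0.00617) among 24 tested; adjusted over the list alone, 6 fell and 2 rose, and Fgf15 differed by 0.37 (adjusted p = 0.0984). The list mean differed by -0.22 in slide 1 and -0.18 in slide 2 (exact permutation p = 0.0286). With the mean of a gene's probes the list did not pass (adjusted p = 0.0819).

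Of the lists of markers of other tissues, 3 passed with the preset correlation and 0 with an estimated one or by fry. Genes of the yolk sac and visceral endoderm were higher as a list (camera adjusted p = 8.2e-06, median 1.60), with 20 of 20 members above 0 and 0 past the threshold. Apob, an apolipoprotein, differed by 2.82 (adjusted p = 0.222). With an estimated correlation, which was 0.918, the adjusted p = 0.569, and the list mean of Hoxa1 null pool 2 (-0.43) lay below those of wildtype pools 3 (0.68) and 4 (0.73). The mean differed by 1.48 (exact permutation p = 0.114), by 1.37 in slide 1 and 1.60 in slide 2. Primitive blood genes were higher as a list (camera adjusted p = 0.00344, median 0.46, adjusted p = 0.499 with an estimated correlation), with 14 of 14 members above 0, 0 past the threshold and a difference in means of 0.80 (exact permutation p = 0.0286), 0.79 in slide 1 and 0.81 in slide 2. That list did not pass with array weights (median 0.34, adjusted p = 0.0558). Nor did it pass without Hoxa1 null pools 2 and 4, where the median was 0.23 (adjusted p = 0.194). Cardiac genes were higher as a list (camera adjusted p = 0.0364, median 0.47, adjusted p = 0.649 with an estimated correlation), with 0 of 26 past the threshold and a difference in means of 0.41 (exact permutation p = 0.2), 0.66 in slide 1 and 0.16 in slide 2. The cardiac list did not pass without wildtype pools 2 (median 0.29, adjusted p = 0.0931) or 4 (0.47, 0.089), or without Hoxa1 null pools 1 (0.32, 0.17) or 3 (0.25, 0.19). It also did not pass with no background filter (0.42, 0.113) or in slide 2 by itself (0.20, 0.788). With the yolk sac list as a covariate, the cardiac median was 0.17 (adjusted p = 0.538).

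**Figure D3:**
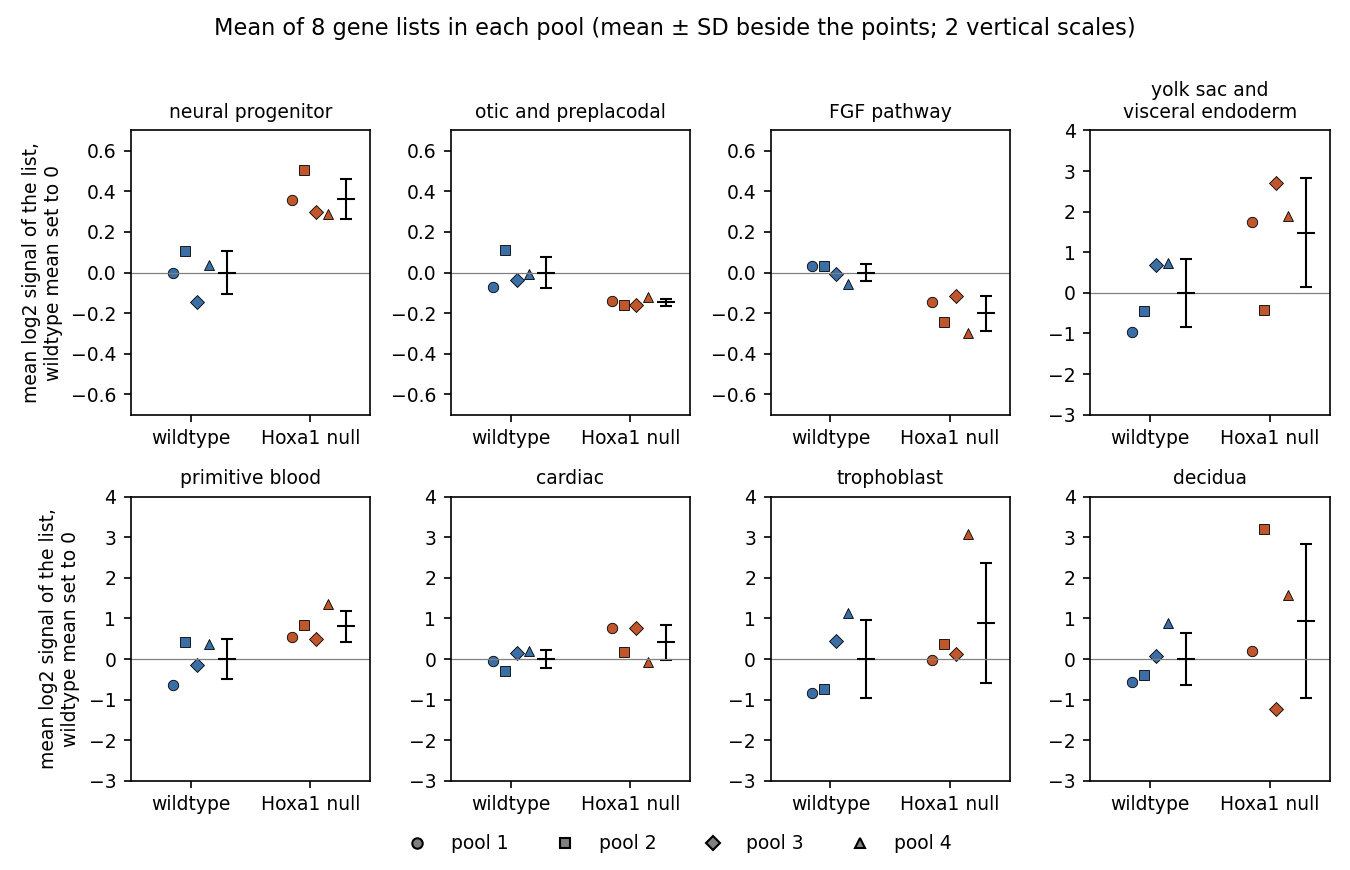
Mean log2 signal of 8 gene lists in each pool, relative to the wildtype mean (vertical axis), with mean ± SD beside the points; the panels have 2 scales, and trophoblast and decidua were added after the data were seen. Hoxa1 null pool 4 lies at 3.07 for trophoblast genes and Hoxa1 null pool 2 at 3.21 for decidua genes.

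In all, 19 of 553 tested list members passed, and 25 of the 31 lists did not pass by camera, of which fry called the WNT and retinoic acid pathways. The exact test of the list mean gave its smallest possible p, 0.0286, for 8 of the 31 lists, or 0.111 after adjustment over the 31. Besides those named with it, these were endothelium (difference 0.21, but 0.11 without Hoxa1 null pool 2) and the BMP pathway (0.06). The count of members past the threshold was 8, 9 and 8 without wildtype pools 1, 2 and 3, and 7 and 9 without Hoxa1 null pools 1 and 3. Neural crest genes had a camera adjusted p of 0.0608 (median -0.06), with Foxd3 lower among 31 tested; adjusted over the list alone, 4 fell, and Erbb3 differed by -0.46 (adjusted p = 0.0586) and Tfap2a by -0.50 (adjusted p = 0.0835). Surface ectoderm genes had a camera adjusted p of 0.0508 (median -0.05), with Krt5 lower among 22; adjusted over the list alone, 5 fell, and Epcam differed by -0.52 (adjusted p = 0.0519). WNT pathway genes had a camera adjusted p of 0.0574 (fry adjusted p = 0.0432, median -0.10, mean 0.06 in slide 1 and -0.10 in slide 2), with Sp5, a zinc finger target of WNT signalling, lower (-0.62, adjusted p = 0.0249). Sp5 passed in 2 of 8 fits with a pool left out. When adjusted over the list alone, 4 fell and 1 rose. NOTCH pathway genes (camera adjusted p = 0.255, median 0.10) held a rise of the ligand Dll4 (0.72, adjusted p = 0.0266) and the fall of Dner. Dll4 passed in 2 of 8 fits with a pool left out and Dner in all 8. When adjusted over the list alone, 6 rose and 1 fell, and Heyl differed by 0.91 (adjusted p = 0.0787). Retinoic acid pathway genes (camera adjusted p = 0.447, fry adjusted p = 0.0432, median 0.07) had 0 of 22 past the threshold. Their mean was higher in each Hoxa1 null pool than in any wildtype pool (difference 0.21, 0.22 in slide 1 and 0.20 in slide 2, exact permutation p = 0.0286). Without Rbp4, which is also in the yolk sac list, the difference was 0.13 (0.14 in slide 1 and 0.12 in slide 2, exact permutation p = 0.0286), and fry did not call the list (adjusted p = 0.0568). Adjusted over the list alone, 2 rose and 1 fell, and Dhrs3 differed by 0.95 (adjusted p = 0.0662).

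Near Hoxa1 on chromosome 6, Jazf1 rose by 0.82 (SE 0.07, adjusted p = 0.00588) and Snx10 fell by 0.43 (SE 0.07, adjusted p = 0.049), while another probe of Snx10 differed by 0.10 and its call was lost in all 8 fits with a pool left out. The list of 17 tested genes that flank the Hoxa cluster did not pass (camera adjusted p = 0.893, median 0.01); adjusted over the list alone, 1 rose and 2 fell. Within 20 Mb of Hoxa1 and with Hox genes left out, 8 of 271 tested genes passed (2.95%), 7 lower and 1 higher, compared with 65 of 18564 genes elsewhere (0.35%). The odds ratio was 8.66 (95% interval 3.55 to 18.3, two-sided Fisher's exact test p = 9.9e-06, with genes as the units). Among the 8, the probe of LOC14210 (at 50153057) lies between probes of Gsdme (at 50150228 and 50157436). The same locus may thus be counted more than once. Neighbouring genes in the same pools are not independent units, so the interval and p may be too sharp.

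**Figure D4:**
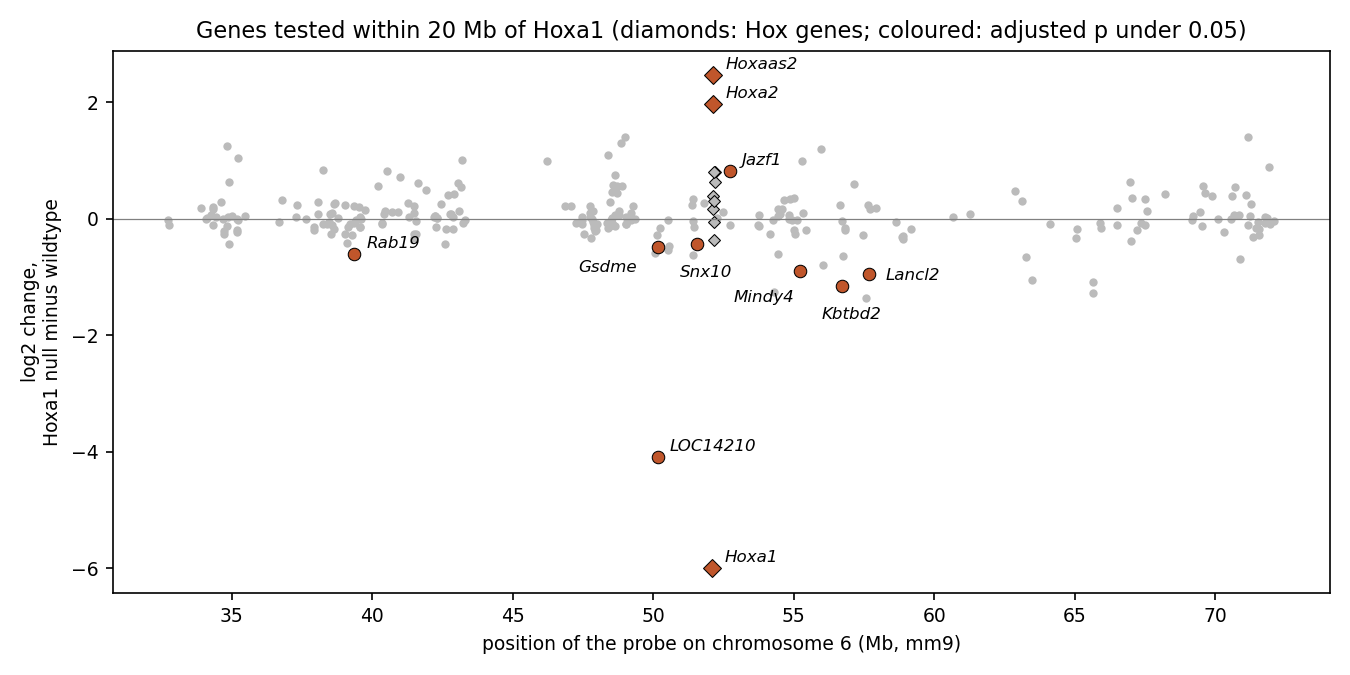
Log2 change (Hoxa1 null minus wildtype, vertical axis) of the genes tested within 20 Mb of Hoxa1 by probe position on chromosome 6 (mm9, Mb); diamonds are Hox genes and coloured symbols passed at an adjusted p under 0.05. Of the coloured symbols that are not Hox genes, 7 lie below 0 and 1 above.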

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

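Chosen only after the results were seen were the tests of the inherited segment, of loss of the protein near the cluster, of yolk sac carry-over, of a genotype effect on yolk sac genes, of a local effect on Hoxa2, of a larger rhombomere 3 territory, and the splits for the gene count; the probe mismatch test and the splits for lists and list members were set before.

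In 9 of 112 groups of 4 pools, 1 pool lay far from the other 3, where chance gives about 5.6. Chrna5 was -4.32 in wildtype pool 4 (others -3.89 to -3.85), Krt5 was -1.61 in Hoxa1 null pool 2 (others -2.32 to -2.26), and Cfap100 was -6.74 in wildtype pool 1 (others -6.32 to -6.23). Of list means relative to wildtype, rostral brain genes were at -0.067 in Hoxa1 null pool 4 (others -0.47 to -0.43), endothelial genes at 0.49 in Hoxa1 null pool 2 (others 0.09 to 0.15) and hypoxia and glycolysis genes at 0.10 in Hoxa1 null pool 4 (others 0.00 to 0.02). Sex-linked genes were at -0.33 in wildtype pool 3 (others 0.10 to 0.12), and trophoblast genes at 3.07 in Hoxa1 null pool 4 (others -0.02 to 0.36). The share of probes well above background was 68.6% in Hoxa1 null pool 1 (others 71.2% to 71.4%).

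Yolk sac genes ranked the pools almost alike: Kendall's W over the 20 members was 0.918, with Hoxa1 null pool 2 the lowest and pool 3 the highest Hoxa1 null pool in 20 of 20 members, and the means of the Hoxa1 null pools spanned 3.13 against a difference of 1.48 between genotypes. This is consistent with tissue of the yolk sac carried over in differing amounts, a hypothesis; of the 20 members 2 are also in another list, 19 were above background on every wildtype array, and Rbp4, also in the retinoic acid list, averaged 1.70 in wildtype and 3.50 in Hoxa1 null pools. The members of highest signal moved less, Apoe from 5.06 to 5.28 and Lrp2 from 3.56 to 3.88, though signals of different probes do not rank abundance. A genotype effect that places every Hoxa1 null pool above every wildtype pool was not seen. The lowest Hoxa1 null pool (-0.426) lay below the wildtype median (0.11) and below wildtype pools 3 (0.68) and 4 (0.73). This argues against such an effect on the list mean. A weaker effect within the spread of the pools stays open, since that pool lay within 1 wildtype SD (0.84) of the wildtype mean. No sort or gate that would remove yolk sac tissue is given in the sources used here.

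Genes past the threshold were more frequent within 20 Mb of Hoxa1 (odds ratio 8.655), as a chromosome segment inherited with the null allele would give, a hypothesis. Probes that mismatch a strain variant would leave the other probes of these genes near 0; their median change in the direction of the call was 0.315 over 4 genes, with Kbtbd2 at -0.57, Lancl2 at -0.40, Gsdme at -0.23 and Snx10 at 0.10. That lies above both the bound of 0.3 set beforehand and its median absolute deviation (0.17), which argues against a mismatch, but passes the bound by less than that deviation, so that a mismatch stays open. Loss of Hoxa1 protein cannot be told apart from the segment with 1 allele, whether for Snx10 (-0.4285), the nearest gene past the threshold outside the cluster, or for the others.

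Hoxa2 rose while Hoxb2 differed by -0.91. The difference of 2.883 (SE 0.20) between them restates changes that had been seen before the test was set, so it lends no support to a local effect of the altered allele, which stays open. A larger territory of rhombomere 3 stays open: Egr2 differed by 0.5976 and did not pass, and as it also marks rhombomere 5 its change mixes both.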

How the results depend on the processing

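Chosen after the data were seen were the covariates, leaving out Hoxa1 null pools 2 and 4 together, the retinoic acid list without Rbp4, and the maximum likelihood and bright-spot versions of normexp. Hoxa1 stayed past the threshold in all 27 alternatives run for it (log2 change -6.15 to -5.09, highest adjusted p 0.039). The 77 genes kept their sign in every alternative that tested them other than normexp with the 75th percentile, by either fit, where 60 of 77 did. The filter on all 8 arrays tested 67 of them. With every probe by itself, the sign was that of each gene's probe of lowest p. Of 27 tested probes other than those that represented these genes, 5 went the opposite way. These were probes of Ebf4 (-0.13), Hnf1b (0.03), Nkx1-2 (0.23), Peak1 (0.35) and Snx10 (0.10). With the slides apart, pools left out or array weights, the sign is fixed, since the pools of one genotype lie beyond those of the other in all 77. It is also fixed with the slide or replicate number as a block and with a variance trend, which leave the difference in means as it is.

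Counts are given as genes past the threshold, then lower and higher. There were 105 (78 and 27) after quantile normalisation, 38 (25 and 13; 10 lists, 9 list members) with no background filter, and 58 (51 and 7; 12 list members) in the value table. The slide as a block gave 72 genes and 10 lists, with 60 of the 77 genes kept. Slide 1 by itself gave 2 (2 and 0; 11 lists, 0 list members) and slide 2 by itself 1 (1 and 0; 0 list members), with fewer pools. A variance trend gave 143 (86 and 57; 12 lists, 29 list members), and array weights 266 (139 and 127; 11 lists, 44 list members), with 66 and 77 of the genes kept. Thresholds of 0.01 and 0.1 gave 22 (17 and 5) and 182 (110 and 72). The replicate number as a block gave 26 (17 and 9; 8 list members), 18 of them among the 77. With an estimated correlation, 0 lists passed, against 5 by fry and 6 on ranks. Where no construction explains a difference, the cause was not tested.

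Normexp with the 75th percentile gave 1 gene (1 and 0; 0 list members; 467 genes at an unadjusted p under 0.05). On the Hoxa1 null 1 array, 14 spots had a local background more than 200 above their signal (up to 136021, against at most 36.5 elsewhere), and the 1st percentile of its normexp log2 signal was 10.6, against 5.81 to 5.84 on the other arrays. A maximum likelihood fit, tried next, also gave 1 (1 and 0; 0 list members), with that percentile at 10.7; without those spots it was 6.11, and 53 genes passed (31 and 22; 14 lists), 42 of them among the 77. Normexp with quantile normalisation gave 98 (71 and 27). Under normexp with the 75th percentile, changes reversed for Cryba2 (0.58), Chrna5 (0.22), Fezf2 (0.59), Nkx1-2 (0.093), Pax8 (0.33), Hoxb3 (0.042), Fgf9 (0.32), Fzd8 (0.082), Rab19 (0.36), Mindy4 (0.19), Apoe (-0.099) and Lrp2 (-0.025); by maximum likelihood these were 0.58, 0.22, 0.59, 0.091, 0.33, 0.040, 0.32, 0.080, 0.35, 0.19, -0.11 and -0.034.

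With the yolk sac covariate, 29 genes passed (20 and 9; 11 lists, 10 list members), 23 of them among the 77, and Apoe, a member of the covariate, reversed (-0.16), and with decidua and trophoblast covariates 33 (24 and 9; 11 lists, 9 list members), 30 of them among the 77. Without Hoxa1 null pools 2 and 4 there were 61 (44 and 17; 11 lists), 33 of them among the 77. Leaving out 1 pool at a time gave 28 to 153 genes (20 to 73 lower, 7 to 80 higher), 5 to 12 lists and 7 to 22 list members, and the 37 named genes other than Hoxa1 that passed stayed past the threshold in 162 of 296 such fits and missed it, with the same sign, in 134. For them, 315 of 436 values under the alternatives fixed beforehand that kept all 8 pools stayed past the threshold, 114 did not and 7 reversed, while all 74 within a slide missed it. Several of these alternatives could not reverse a sign, as given above. Signal over background limits the genes given as bounds and Olfr648, Cfap100, Hoxb4 and LOC14210.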

Other observations

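The tests of splits for genes were chosen after the count was seen, and so were the lists of trophoblast and decidua genes; the splits for lists and list members were set before.

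The remaining lists fixed before the data were examined did not pass. Rostral brain genes had a camera adjusted p of 0.0608 (median -0.22), with the fall of Lhx5 as the 1 change among 10 tested, also adjusted over the list alone. Caudal axis genes (adjusted p = 0.938) held the fall of Nkx1-2 (-0.60, adjusted p = 0.0233), of which another probe differed by 0.23. In the TALE list (adjusted p = 0.232, median -0.02), the Hox cofactor Meis3 fell by 0.49 (adjusted p = 0.0287) among 11 tested. With a pool left out, Meis3 passed in 1 of 8 fits and Nkx1-2 in 3. Guidance genes of the Eph and semaphorin families (adjusted p = 0.755) held the fall of Epha2; adjusted over the list alone, 3 fell. Neuronal differentiation genes (adjusted p = 0.474, median 0.16) had 0 of 20 past the threshold, with Stmn2 at 0.68 (adjusted p = 0.0519); adjusted over the list alone, 1 rose and 1 fell.

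No gene passed in the other lists, whose camera adjusted p values were 0.429 for posterior Hox genes, 0.154 for endoderm, 0.447 for paraxial mesoderm, 0.208 for endothelium, 0.0725 for myeloid genes, 0.938 for the BMP pathway, 0.617 for hedgehog, 0.0725 for the cell cycle, 0.77 for p53 and apoptosis, 0.229 for immediate early and stress genes, 0.884 for hypoxia and glycolysis, and 0.062 for sex-linked genes. Adjusted over the list alone, 4 sex-linked, 4 endoderm, 2 apoptosis, 1 endothelial and 1 hypoxia gene fell, and 1 paraxial mesoderm gene rose and 1 fell. The 4 sex-linked genes were Ddx3y (-1.40), Eif2s3y (-1.41), Kdm5d (-1.39) and Uty (-1.92), all on chromosome Y. The sex of the embryos was not among the sample variables used here, so these 4 differences cannot be assigned to genotype. The other 2 tested members of that list were above 0. The direction of the test differed from the sign of the median or mean in caudal axis (lower, median 0.01, mean 0.10), hedgehog (lower, median 0.01, mean -0.04), guidance (lower, median 0.06, mean -0.05), hypoxia (lower, median 0.01, mean 0.03) and Hoxa flank genes (higher, median 0.01, mean -0.02).

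Among pools, decidua genes, from the maternal uterus, stood at 3.21 in Hoxa1 null pool 2 and 1.58 in pool 4, and at -1.23 in pool 3, relative to wildtype. The mean of sex-linked genes was -1.53 in Hoxa1 null pool 3 and -1.38 in pool 4 (difference between genotypes -0.88, exact permutation p = 0.0571). The first principal component held 40.4% of the variance, with Hoxa1 null pools 2 and 4 at 47.7 and 39.4 and the other pools from -36.1 to 4.64.

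LOC14210, a clone name and chosen here after its values were seen, differed by -4.10 (SE 0.56, adjusted p = 0.0267), but was above background on 2 of the 4 Hoxa1 null arrays, where the size is uncertain, and passed in 2 of 8 fits with a pool left out. The other genes past the threshold near Hoxa1, also chosen after, were Rab19 (-0.61), Gsdme (-0.49), Mindy4 (-0.90), Kbtbd2 (-1.15) and Lancl2 (-0.95). With a pool left out, Mindy4 and Kbtbd2 passed in all 8 fits, Rab19 in 1, Gsdme in 2 and Lancl2 in 3.

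Of the 35 splits of the 8 pools into 4 and 4, 1, the real one, gave 77 genes or more, and the highest other gave 1. A share of 1 in 35 is the smallest that these splits can give. The other splits mix the genotypes, and the test was chosen after the count was seen, so it cannot exclude chance. For list members past the threshold, again 1 split, the real one, reached 19, and the highest other gave 0. For lists, 8 of the 35 splits gave 6 or more and the highest other gave 10, so that chance is not excluded for the count of lists.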
